A study of Sus scrofa with 8 samples.

How the data were processed

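Lung RNA from pigs of 2 breeds, Landrace and Tongcheng, was sequenced before (0 days post infection, dpi) and at 3, 5 and 7 dpi with highly pathogenic porcine reproductive and respiratory syndrome virus (HP-PRRSV), an RNA virus that infects pig macrophages. Per the labels, each of the 8 libraries held equal amounts of total RNA from 3 pigs aged 35 days, so each breed and day had 1 pool. The values of the 2 deposited tables, 1 per breed, were RPKM as the authors made them, that is read numbers scaled to gene length and to the library's total, and the breed of each table was taken from its name. Per the submitters' processing notes, reads were aligned with Bowtie2. The version, the counting tool, the annotation release and the genome build were not given in the sources used here.

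Both tables listed the same 25322 Ensembl gene IDs. Gene symbols were matched for 11804 IDs (46.6%), and where several IDs had 1 symbol the ID with the highest mean RPKM was used. CD163, the main entry receptor of the virus, had no named ID and was not analysed here. Whole reads and gene lengths were worked back from the steps between low RPKM values. Of 138238 values above 0, 138238 came out whole within a relative tolerance of 1e-10, and the recomputed RPKM differed by at most 1.3e-13. Library totals lay between 16538368 and 33984228 reads, so 3 reads of a 1 kb gene stood for 0.0883 to 0.181 RPKM. Gene coordinates and GC content were not used here.

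Tests ran on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend of the variance on expression and two-sided p-values adjusted by Benjamini-Hochberg. A log2 difference on this scale understates changes of genes with low RPKM. Genes with an RPKM of 1 or more in at least 2 libraries were tested (13739, of which 8822 had a symbol), and an adjusted p under 0.05 was called. The comparisons were infected against uninfected pools with breed in the model, each day against 0 dpi and Tongcheng against Landrace from 1 fit of breed and day, and the interaction of breed with infection. Residual degrees of freedom were 5, 3, 3, 3, 3 and 4 in that order. A day or a 0 dpi group within a breed was 1 pool, assumed to vary like the others. No breed and day had more than 1 pool, so the p-values rest on neither replicate pools nor single pigs. In the fit of breed and day, the residual spread holds any breed difference in the change over days, together with variation between pools. In the infection test it also holds differences between the infected days. In the interaction test it holds such day differences within each breed, and pool variation. Each library had been normalised to its own total with the same gene lengths in both tables, which is what the comparison of levels across the tables rests on.

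Of 33 gene lists fixed before the data were examined, 30 had at least 3 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Ratios of 2 single pools had no test: genes with an RPKM of 1 or more in either pool and a difference of at least 2-fold were counted, and the median of each list was placed among 10000 random lists matched on mean expression in 20 bins. The 13 mitochondrially encoded genes were added as a list after the data were seen. Their camera p-values were not adjusted over the lists. Named genes followed a rule fixed beforehand. For the infection, breed and interaction tests it took up to 12 genes with a symbol in each direction, filled to 5 with genes that did not pass. For each day it took 5 in each direction that passed, for each breed's time course 5, for each ratio of the breeds 3, and from each list up to 4 members. SIGLEC1 was always included. A few genes that the rule or the lists would name are not reported here.

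The tests were run on simulated libraries in which 200 genes were changed, 20 times for each of 3 ways of drawing the spread. The spreads were the fitted prior, the residual SD and the posterior SD, and the values follow in that order. Of 13379 to 13475 genes tested, a log2 change of 2 was called in 28.6%, 16.8% and 62.2% at 3 dpi, 26.8%, 18.1% and 61.4% at 5 dpi, and 28.3%, 17.2% and 63.6% at 7 dpi. For breed it was called in 84.3%, 59.0% and 97.6% and for infection in 37.2%, 40.6% and 57.2%. For the interaction, a change of 4 was called in 0.6%, 0.0% and 24.9%. The false share of calls was averaged over simulations, with 0% for a simulation without calls. It was 5.8%, 3.5% and 7.2% for breed, and 6.0%, 5.0% and 11.4% for the interaction. The interaction had a mean of only 0.4, 0.0 (rounded) and 17.6 calls per simulation, with 0.15, 0.05 and 2.10 false. Its low shares under the fitted prior and the residual SD therefore do not show that its calls were mostly true. Simulated lists of 15 genes shifted by a log2 of 1 were called by camera in 100% of cases for breed and 87% for the interaction, with 0.4% and 1.2% of unshifted lists. Simulated libraries and genes were drawn independently and held no library-wide departure, which real pools can have. The interferon-stimulated genes had an estimated correlation of 0.874 at 3 dpi. The simulated lists therefore do not show the error rate of camera for lists whose genes vary together. Random lists fell outside the central 95% of the percentile scale in 3.5% of cases for Tongcheng at 3 dpi and 6.8% for Landrace at 5 dpi. The genes of these lists were drawn at random. These shares therefore do not show how often lists whose genes vary together fall outside.

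Alternatives set beforehand were a pseudocount of 0.1, no filter or a mean RPKM of 5, median-of-ratios scaling, quantile normalization, no trend, robust fitting, a threshold of 0.1, other model terms, and leaving out each pool. The limma voom fit of the worked-back reads, removal of a gene-length trend from each library and list tests without the Landrace 0 dpi pool were added after seeing the data. Figures were drawn with matplotlib 3.10.9, and tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.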

Results

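The series asked how the lungs of Landrace and Tongcheng pigs, a commercial and a Chinese indigenous breed, differ in gene expression after infection with HP-PRRSV. Each breed had 1 pool of 3 pigs at 0, 3, 5 and 7 dpi, giving 8 libraries. They held 21660490, 26897200, 23848030 and 33841856 reads in Landrace and 16538368, 31856883, 27828889 and 33984228 in Tongcheng. The Landrace 0 dpi pool lay apart from the others on the first principal component (-90.7, against -40.5 to 56.9 for the other 7), which held 43% of the variance. The 13 mitochondrially encoded genes took 16.4% of its reads, 5.62% in the Tongcheng 0 dpi pool and 19.8% in the Tongcheng 7 dpi pool. Pools of different breeds on the same day correlated across genes at 0.913, 0.925, 0.952 and 0.917 for 0, 3, 5 and 7 dpi.

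In Landrace, type I interferon-stimulated genes, the antiviral program that cells start after sensing a virus, were higher on every day than in the 0 dpi pool. The median log2 ratio of 30 genes was 2.88, 2.30 and 2.22 at 3, 5 and 7 dpi, above all 10000 matched random lists on each day. RSAD2, an antiviral enzyme, had an RPKM of 7.56 at 0 dpi and 348, 218 and 282 afterwards, and MX1, which blocks virus replication, 7.44 and then 125, 109 and 157. In Tongcheng the median was 0.53, 0.79 and -0.25, at percentiles 99.9, 100 and 78.2. MX1 had an RPKM of 60.6 in the Tongcheng 0 dpi pool and 100, 194 and 94.5 afterwards. Smooth muscle markers had median ratios of -1.55, -2.29 and -0.83 in Landrace and -0.19, -1.01 and 0.09 in Tongcheng, and extracellular matrix genes -1.06, -1.97 and -1.29 against -0.36, -1.01 and -0.42. Erythroid and platelet genes, a sign of blood in the tissue, were at -2.32, -3.00 and -2.09 in Tongcheng and -0.02, -0.83 and -2.27 in Landrace (3 genes). By size, the named genes included S100A6, a calcium-binding protein, at a mean log2 of 5.90 over the 3 Landrace days (SD 1.22), SNRPF at 5.56, SNRPE at 5.44 and ISG20 at 5.28. SLIT3 stood at -3.77 and MARCO, a macrophage scavenger receptor, at -3.86 (SD 3.32). In Tongcheng they included the chemokine CCL2 at 2.87 (SD 1.93), NDUFB1 at 3.18, the globin genes HBM and HBB at -2.93 and -2.40, and CYP1A1 at -2.62.

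Counts of genes at least 2-fold apart were 5952, 5759 and 3633 in Landrace at 3, 5 and 7 dpi and 1770, 2806 and 3241 in Tongcheng. These ratios compare 1 pool with 1 pool and have no replicate check, and the 3 ratios of a breed share its 0 dpi pool. Higher and lower genes numbered 3270 and 2682, 2736 and 3023, and 2227 and 1406 in Landrace, and 1306 and 464, 921 and 1885, and 799 and 2442 in Tongcheng. After median-of-ratios scaling the Tongcheng split was 856 and 618, 1380 and 1047, and 1520 and 886, so its direction turned at 5 and 7 dpi. The Landrace split at 5 dpi was then 3160 and 2662. Gene length moved with the Landrace ratios: at 5 dpi the median log2 was 0.378 for the shortest genes (up to 611 bp) and -0.519 for the longest (from 5113 bp), against -0.011 and -0.347 in Tongcheng.

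**Figure D1:**
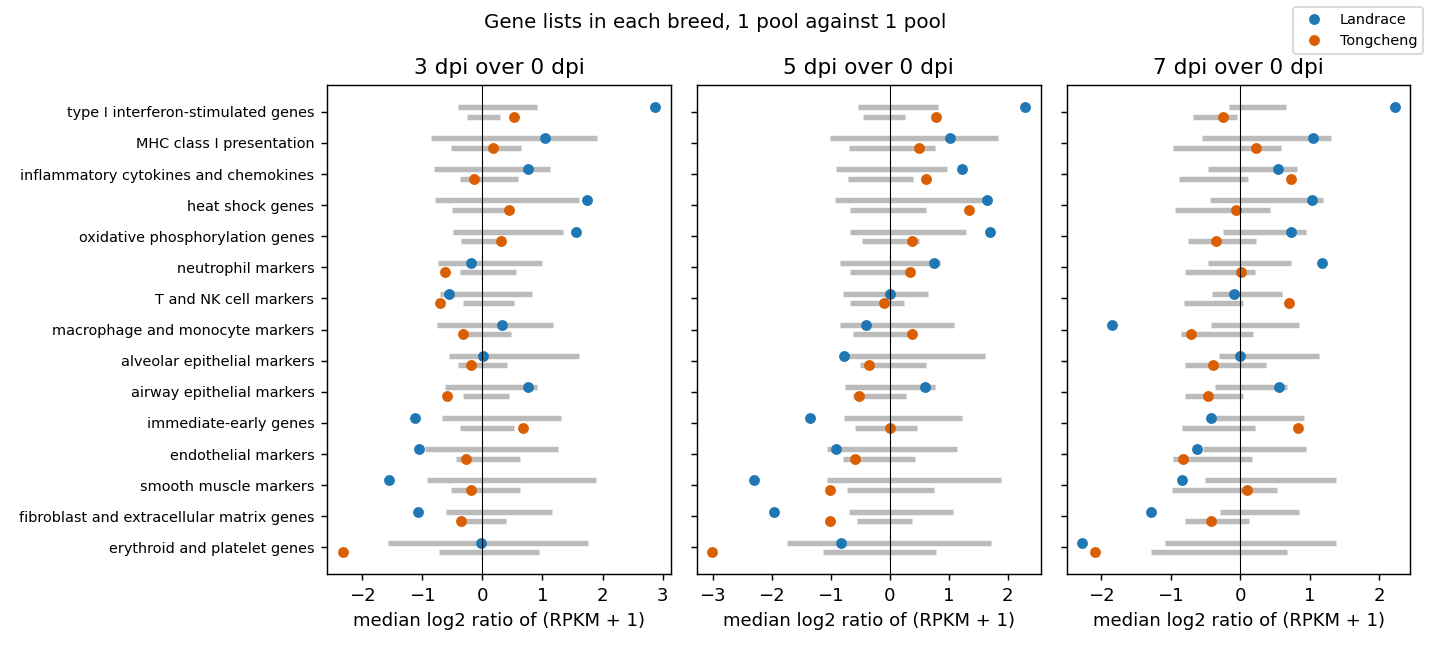
Median log2 ratio of (RPKM + 1) of 15 gene lists at 3, 5 and 7 dpi over 0 dpi, with Landrace in blue and Tongcheng in orange; grey bars span the central 95% of 10000 random lists matched on mean expression. Interferon-stimulated genes in Landrace lie at 2.88, 2.30 and 2.22, to the right of their bars on all 3 days.

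Across all 6 infected pools against the 2 pools at 0 dpi, no single gene passed, although interferon-stimulated genes lay higher as a list. Their median log2 difference was 1.33 (29 of 30 positive; limma camera adjusted p = 8.15e-11, and adjusted p = 0.502 with an estimated correlation). When adjusted over the list alone 14 of them rose, RSAD2 by 3.01 ± 0.736 (SE), IFIT1 by 2.93 ± 0.782, ISG20 by 3.04 ± 0.901 and MX1 by 2.48 ± 0.598. Without the Landrace 0 dpi pool the list median was 0.24 (limma camera adjusted p = 0.00501), and RSAD2, IFIT1, ISG20 and MX1 were at 0.99, 1.01, 0.81 and 1.01; without the Tongcheng 0 dpi pool they were at 5.03, 4.85, 5.28 and 3.94. Oxidative phosphorylation genes of the nucleus had a median of 0.63 (17 of 17 positive; limma camera adjusted p = 0.000276, 0.553 with an estimated correlation; 1 adjusted over the list alone, CYCS, the electron carrier cytochrome c, 3.10 ± 0.65). Mitochondrially encoded genes had a median of -0.27 (limma camera p, without adjustment, 0.952). Without the Landrace 0 dpi pool camera placed these genes higher instead of lower. Extracellular matrix genes had a median of -0.95 (13 of 16 negative; limma camera adjusted p = 0.00319, 0.502 with an estimated correlation; 4 adjusted over the list alone, among them FN1, fibronectin, at -1.82 ± 0.54). ALAS2, the first enzyme of heme synthesis in red cells, was at -2.21 ± 0.401 and 2 of the 3 erythroid and platelet genes were lower over the list alone (limma camera adjusted p = 0.01, 0.502 with an estimated correlation). The median log2 level of the 3 genes was 7.24 in the Tongcheng 0 dpi pool and 4.04 in the Landrace 0 dpi pool. Over the alternatives HBM ran from -2.93 to -0.32, HBB from -2.40 to -0.51 and ALAS2 from -2.91 to -1.95. The limma camera test at the preset correlation also called heat shock genes (0.86, 0.00297), ribosomal protein genes (0.66, 0.00319) and endothelial markers (-0.75, 0.0212). They had 1, 3 and 2 members passing when adjusted over the list alone, and adjusted p = 0.502, 0.535 and 0.502 with an estimated correlation. Without the Landrace 0 dpi pool the medians were -0.61 for extracellular matrix (limma camera adjusted p = 0.113), 0.14 for oxidative phosphorylation (0.0715), 0.12 for ribosomal protein (0.0377) and -0.60 for endothelial genes (0.0641). FN1 was then at -0.60 (-3.03 without the Tongcheng 0 dpi pool) and CYCS at 1.83. With the length trend removed the adjusted p of endothelial markers was 0.0997. SIGLEC1, a macrophage receptor that binds the virus, and the virus's attachment factor HSPG2 belong to the entry factor list (median -0.86, limma camera adjusted p = 0.0703, 0.502 with an estimated correlation; 2 lower over the list alone).

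Of 13739 genes tested, limma called 0, with 2249 at an unadjusted p under 0.05 against 687 by chance and a smallest adjusted p of 0.115, and limma voom on the worked-back reads called 0. Named by the rule although none passed, SNRPF, a core splicing protein, was 4.29 ± 0.723 higher, the protease CTSL 3.96 ± 0.736, S100A6 3.60 ± 0.904, SNRPE 3.58 ± 0.898 and TOMM7 3.52 ± 0.733. The cartilage collagen COL2A1 stood at -3.38 ± 0.482, HSPG2 at -2.79 ± 0.76, SDC3 at -2.54 ± 0.713, MARCO at -2.46 ± 1.31 and ANO2 at -2.46 ± 0.456. S100A6 was at 1.31, SNRPE at 1.71, HSPG2 at -1.80, SDC3 at -1.33 and MARCO at -1.07 when the Landrace 0 dpi pool was left out (MARCO at -1.59 without the Landrace 7 dpi pool). Without the Tongcheng 0 dpi pool S100A6 was at 5.90, SNRPE at 5.44 and MARCO at -3.86. The count was 1 with a pseudocount of 0.1, and 12, all lower, without the filter on low values. It was 3 without the Tongcheng 0 dpi pool, 4 without the Tongcheng 7 dpi pool and 1 without either 3 dpi pool.

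At 3 dpi, 35 genes rose and 2 fell in both breeds' common contrast. Among genes with a symbol the largest rises were those of TOMM7, of the mitochondrial import pore (4.25 ± 0.671, limma adjusted p = 0.0442), NDUFB1, of respiratory complex I (3.78 ± 0.567, limma adjusted p = 0.0402), POLR2K, of RNA polymerase II (3.77 ± 0.596), LSM5, of the RNA-processing LSM ring (3.67 ± 0.561), and SLIRP, which stabilises mitochondrial mRNA (3.60 ± 0.415). COL2A1 fell by 3.38 ± 0.51. The 35 genes that rose had a median length of 451 bp, against 1965 bp over all genes tested, and 22 of them had no symbol. No list member passed over all genes. Oxidative phosphorylation genes had a median of 0.98 (17 of 17 positive, 6 over the list alone; limma camera adjusted p = 0.000756, 0.772 with an estimated correlation), and interferon-stimulated genes 1.67 (27 of 30, 15 over the list alone; 1.2e-05, 0.772 with an estimated correlation). Mitochondrially encoded genes, the list added after seeing the data, went the other way (median -1.20, 12 of 13 negative). Their limma camera p, without adjustment, was 0.00449, and 0.407 with an estimated correlation. The median log2 level of these genes went from 13.08 at 0 dpi to 11.35 in Landrace and from 11.35 to 10.31 in Tongcheng. The Landrace 0 dpi pool, with 16.4% of its reads in these genes, had the highest level. Over the alternatives ATP8 ran from -2.43 to -0.26 and ND4 from -2.44 to -0.46. The camera test at the preset correlation also called heat shock and ribosomal protein genes as higher, and entry factors, endothelial, smooth muscle and B and plasma cell markers, extracellular matrix, erythroid and proliferation genes as lower. All 11 lists had adjusted p = 0.772 with an estimated correlation. Without the Landrace 0 dpi pool the medians of interferon-stimulated and oxidative phosphorylation genes were 0.54 and 0.44 (limma camera adjusted p = 0.0246 and 0.0168). The adjusted p was 0.0969 for matrix and for ribosomal protein genes, 0.0834 for endothelial and 0.222 for smooth muscle markers, and with the length trend removed 0.0666 for ribosomal protein genes and 0.157 for endothelial markers. The gene calls ended (0) in limma voom, after median-of-ratios or quantile scaling, after removal of the length trend, without a filter, and on leaving out the Landrace 0, 3 or 7 dpi or the Tongcheng 7 dpi pool, while 3435 genes had an unadjusted p under 0.05 in the limma test. The median of all genes was 0.10, 0.015 after median-of-ratios scaling and -0.026 after quantile normalization. Without the Tongcheng 0 dpi pool 1615 genes were called, without the Landrace 5 dpi pool 321, without the Tongcheng 3 dpi pool 232 and without the Tongcheng 5 dpi pool 327.

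At 5 dpi limma called 281 genes higher and 377 lower. Collagens and other matrix genes fell: COL6A3 (-2.75 ± 0.425), COL5A1 (-2.53 ± 0.408), COL1A2 (-2.23 ± 0.532) and TNC, the matrix glycoprotein tenascin (-3.09 ± 0.739), passed over all genes, and 9 of 16 were lower and 1 higher over the list alone (median -1.40, limma camera adjusted p = 0.00298, 0.588 with an estimated correlation). The contractile genes CNN1 (-2.39 ± 0.545) and ACTG2 (-1.99 ± 0.458) fell too (median of 6 smooth muscle markers -1.68, 3 over the list alone; 0.0102, 0.588 with an estimated correlation). Among the entry factors, SIGLEC1 (-1.89 ± 0.388, limma adjusted p = 0.042) and HSPG2, the heparan sulfate proteoglycan perlecan (-3.66 ± 0.563), fell, and 4 of 7 were lower and CD209 higher over the list alone (limma camera adjusted p = 0.045, 0.588 with an estimated correlation). The chaperones HSPE1 (3.04 ± 0.672), HSPA8 (2.82 ± 0.62) and HSPD1 (2.79 ± 0.55) rose (median of 9 heat shock genes 1.30, 4 over the list alone; 0.000244, 0.588 with an estimated correlation), as did the respiratory chain genes CYCS (3.66 ± 0.667), NDUFB5 (3.05 ± 0.64) and NDUFA4 (2.48 ± 0.53; median of 17 genes 1.12, 5 over the list alone; 5.66e-05, 0.588 with an estimated correlation). Mitochondrially encoded genes had a median of -0.32, with 6 of 13 positive (limma camera p, without adjustment, 0.799). From 0 to 5 dpi the median log2 level of these genes fell from 13.08 to 11.96 in Landrace and rose from 11.35 to 11.64 in Tongcheng. On leaving out the Landrace 0 dpi pool TNC was at -1.77, COL1A2 at -1.44, CNN1 at -1.47, HSPE1 at 1.89, HSPA8 at 1.76, HSPD1 at 1.83, CYCS at 2.39 and NDUFB5 at 1.98.

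None of the 30 interferon-stimulated genes passed over all genes at 5 dpi, and 13 rose when adjusted over the list alone, among them ISG20 by 3.69 ± 1.08 and IFIT1 by 3.48 ± 0.905 (median 1.60, limma camera adjusted p = 6.12e-08, 0.588 with an estimated correlation). Inflammatory cytokines (median 0.90, 0.0296, none over the list alone), acute-phase and metallothionein genes (1.41, 0.0346, 2 over the list alone) and ribosomal protein genes (1.29, 0.000407, 2 over the list alone) were also called by limma camera as higher. All had adjusted p = 0.588 with an estimated correlation. The acute-phase and metallothionein list, named acute-phase genes below, had only 3 tested members. Its 1 member that passed over all genes, the metallothionein MT3, kept its call in 5 of 18 alternatives. With the Landrace 0 dpi pool left out ISG20 was at 1.46 and IFIT1 at 1.56, and the list medians were 0.47 for interferon-stimulated, 0.53 for oxidative phosphorylation, 0.62 for ribosomal protein, -0.86 for matrix and -1.08 for smooth muscle genes (limma camera adjusted p from 0.000743 to 0.0487). With the length trend removed the adjusted p was 0.0786 for entry factors and 0.0513 for acute-phase genes. Single members of lists that camera did not call passed as well: the interferon-induced chemokine CXCL11 (3.68 ± 0.652), the neutrophil protein S100A8 (3.31 ± 0.769), the cytotoxic protease GZMA (2.72 ± 0.499) and F13A1 (2.54 ± 0.468) rose. VEGFA (-2.07 ± 0.503), ALAS2 (-2.28 ± 0.476), ACTC1 (-1.60 ± 0.343) and ELANE (-1.47 ± 0.352) fell. Among called genes with a symbol and the same direction in both breeds, the largest rise was that of SNRPF (4.87 ± 0.743, limma adjusted p = 0.0385). CTSL (4.63 ± 0.722), S100A6 (4.47 ± 1.03), SNRPE (4.33 ± 0.854) and CHI3L2 (4.02 ± 0.656) came next. Of the 281 genes that rose, 166 had no symbol. The falls, under the same limits, were led by COL2A1 (-3.89 ± 0.51), SDC3 (-3.73 ± 0.615), HSPG2, TNC and SMAD6 (-2.86 ± 0.619). SMAD6 was at -1.82, S100A6 at 2.17 and SNRPE at 2.46 without the Landrace 0 dpi pool. Without the Tongcheng 0 dpi pool S100A6 was at 6.77, ISG20 at 5.93 and IFIT1 at 5.40. Genes that rose had a median length of 820 bp and those that fell 2286 bp. Quantile normalization gave 190 higher and 116 lower, limma voom 309 and 509 (553 shared with the 658), and median-of-ratios scaling, removal of the length trend and no filter 0 in limma, where 4090 genes had an unadjusted p under 0.05. The median of all genes was -0.13, and 0.033 after median-of-ratios scaling. The count was 0 without the Landrace 0 dpi, Landrace 7 dpi or Tongcheng 7 dpi pool, 36 and 191 without the Landrace or Tongcheng 5 dpi pool, 1109 and 1140 without the Landrace or Tongcheng 3 dpi pool and 2136 without the Tongcheng 0 dpi pool.

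At 7 dpi, 4 named genes rose and 1 gene without a symbol fell. MS4A7, a membrane protein of macrophages, rose by 4.43 ± 0.562. The protease inhibitor TIMP1 rose by 4.08 ± 0.508, the secreted phosphoprotein SPP1 (osteopontin) by 4.08 ± 0.484 and SERPINB11 by 3.07 ± 0.393 (limma adjusted p = 0.0458 each, higher in both breeds). TIMP1 went from an RPKM of 81.6 to 2397 in Landrace and from 57.5 to 578 in Tongcheng. Of 12 macrophage and monocyte markers, 4 fell over the list alone, MARCO by 4.64 ± 1.06, the complement component C1QA by 3.79 ± 0.803, SIGLEC1 by 2.44 ± 0.388 and CSF1R by 2.02 ± 0.518 (median -0.85, limma camera adjusted p = 0.0352, 0.736 with an estimated correlation). Without the Landrace 7 dpi pool MARCO was at -2.60 and C1QA at -2.39, and CSF1R was at -1.14 without the Landrace 0 dpi pool and at -3.62 with a pseudocount of 0.1. The neutrophil chemoattractant CXCL2 rose by 3.34 ± 0.595 over the list alone (inflammatory list median 0.52, limma camera adjusted p = 0.0352, 0.736 with an estimated correlation). In the complement and coagulation list F13A1 rose by 2.16 ± 0.468 and C3AR1 fell by 2.22 ± 0.489 (list median 0.37, 0.0352, 0.736 with an estimated correlation).

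The camera test at the preset correlation called 13 lists at 7 dpi, and 0 with an estimated correlation. Interferon-stimulated genes had a median of 0.95 (27 of 30 positive, 0 over the list alone and 0 over all genes by limma; adjusted p = 2.9e-07, 0.736 with an estimated correlation). Without the Landrace 0 dpi pool their median was -0.05 (limma camera adjusted p = 0.491), and 3 of the 13 lists stayed called, the inflammatory, T and NK cell and erythroid lists, with MHC class II (0.0477) and immediate-early genes (5.21e-06) called in addition. The adjusted p was then 0.0854 for macrophage, complement and neutrophil lists, 0.145 for MHC class I, 0.311 for endothelial, 0.157 for adipocyte, 0.278 for acute-phase, 0.547 for heat shock and 0.72 for oxidative phosphorylation genes. The remaining called lists were neutrophil and T and NK cell markers, MHC class I, acute-phase, heat shock and oxidative phosphorylation genes as higher and endothelial, adipocyte and erythroid genes as lower, with limma camera adjusted p from 0.0352 to 0.0435, and 0.736 with an estimated correlation (0.77 for oxidative phosphorylation). Oxidative phosphorylation genes had a median of 0.09 and heat shock genes of 0.38, and -0.42 and -0.20 without the Landrace 0 dpi pool. By median log2 level at 0 and 7 dpi, oxidative phosphorylation genes went from 5.39 to 6.21 in Landrace and from 6.98 to 6.39 in Tongcheng. T and NK cell markers went from 3.26 to 2.77 and from 4.01 to 4.61. Neutrophil markers rose from 3.44 to 5.21 and from 2.27 to 2.49, and the median levels of MHC class I, acute-phase and heat shock lists rose in both breeds. For heat shock genes they went from 5.73 to 5.93 and from 4.94 to 6.34. A median level can rise without a rise of most members, as the -0.20 of heat shock genes without the Landrace 0 dpi pool shows no common rise. Mitochondrially encoded genes had a median of 0.49 (12 of 13 positive), and -0.106 after quantile normalization. Their limma camera p, without adjustment, was 0.00499, and 0.412 with an estimated correlation. The breeds went opposite ways: the median log2 level of these genes fell from 13.08 at 0 dpi to 12.10 in Landrace and rose from 11.35 to 12.96 in Tongcheng. With the length trend removed the limma camera adjusted p was 0.107 for endothelial, 0.0538 for adipocyte and 0.0739 for acute-phase and for oxidative phosphorylation genes. The 5 gene calls became 0 after median-of-ratios or quantile scaling, removal of the length trend, a pseudocount of 0.1 or no filter, and on leaving out the Landrace 0 dpi pool or either 7 dpi pool. They were 2 in limma voom, 124, 122 and 109 without the Landrace 5, Tongcheng 5 or Tongcheng 0 dpi pool and 10 without either 3 dpi pool (1993 genes at an unadjusted p under 0.05 in limma). The median of all genes, -0.153, was 0.011 after median-of-ratios scaling.

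Between the breeds, over all 4 days, 10 genes were higher and 6 lower in Tongcheng. SCGB1A1, the secretory protein of airway club cells, was higher by 4.68 ± 0.611 (limma adjusted p = 0.0268), with an RPKM of 295, 500, 700 and 197 in Tongcheng at 0, 3, 5 and 7 dpi and 60.2, 13.7, 34.4 and 0.498 in Landrace. ADRB3, an adrenergic receptor, was higher by 2.39 ± 0.307 (limma adjusted p = 0.0263), PPM1J, a protein phosphatase, by 2.23 ± 0.263 (0.0189) and STUM by 1.72 ± 0.245 (0.0368). LGALS13, a galectin, was lower (-4.83 ± 0.534, limma adjusted p = 0.0158), with 9.28 to 92.2 RPKM in Landrace and 0.0569 to 0.885 in Tongcheng. All 5 had the same direction on all 4 days, and the other 11 called IDs had no symbol. Y-linked genes and XIST had no tested ID, so the sex of the pools was not checked and is not separated from breed here. Named by the rule without passing, MARCO was higher by 3.11 ± 0.752 and ANKRD1 (-2.49 ± 0.405), the neutrophil granule protein LTF (-2.46 ± 0.42), GNG8 (-2.29 ± 0.439) and SPP1 (-2.25 ± 0.342) were lower.

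No member of 29 of the 30 gene lists passed between the breeds over all genes, SCGB1A1 of the airway list being the exception. Adjusted over the list alone, 5 neutrophil markers were lower in Tongcheng (LTF, MMP8 -1.86, S100A8 -1.70 and LCN2 -1.54 among them; median -0.84, limma camera adjusted p = 1.67e-06, 0.325 with an estimated correlation). Macrophage and monocyte markers had 6 members higher (MARCO, C1QA 1.92, CSF1R 1.73 and CD68 1.70; median 0.996, 0.00307, 0.5 with an estimated correlation) and T and NK cell markers 8 (LCK 1.57, GZMA 1.51, CD8A 1.17, PRF1 1.05; median 0.80, 2.14e-05, 0.524 with an estimated correlation). Interferon-gamma-induced genes had 5 (IDO1 2.29, GBP1 1.81, SLAMF8 1.70; median 0.84, 8.5e-06, 0.5 with an estimated correlation) and MHC class II genes 3 (SLA-DMB 1.31, CTSS 1.29, CIITA 1.19; median 1.0, 0.00052, 0.524 with an estimated correlation). Proliferation genes were positive in 15 of 15 members with none passing over the list alone (median 0.46, 0.00917, 0.82 with an estimated correlation). Mitochondrially encoded genes were negative in 12 of 13 (median -0.58). Their limma camera p, without adjustment, was 1.96e-05, 0.244 with an estimated correlation, and 0.0517 at the preset one without the Landrace 0 dpi pool. The 6 calls of lists fixed beforehand stand beside arbitrary groupings that gave more. There are 8 splits of the 8 libraries with 1 pool of each day in each group. Of these the real one called the fewest lists, and the others called 8 to 17. Without either 7 dpi pool C1QA was at 1.22, CD68 at 1.01 and MMP8 at -0.94, and without either 0 dpi pool CTSS was at 0.78. Without the Landrace 7 dpi or the Tongcheng 7 dpi pool 1 gene was called, without either 0 dpi pool 9 (1 higher, 8 lower), without the Landrace 3 or 5 dpi pool 28 and 40, and without the Tongcheng 3 or 5 dpi pool 30 and 50. Median-of-ratios scaling gave 0 higher and 3 lower, quantile normalization 2 and 5, the length trend removed 4 and 5, limma voom 30 and 23, and no filter 0, where 1368 genes had an unadjusted p under 0.05 in the limma test. The median of all genes, 0.13, was -0.003 after median-of-ratios scaling.

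**Figure D2:**
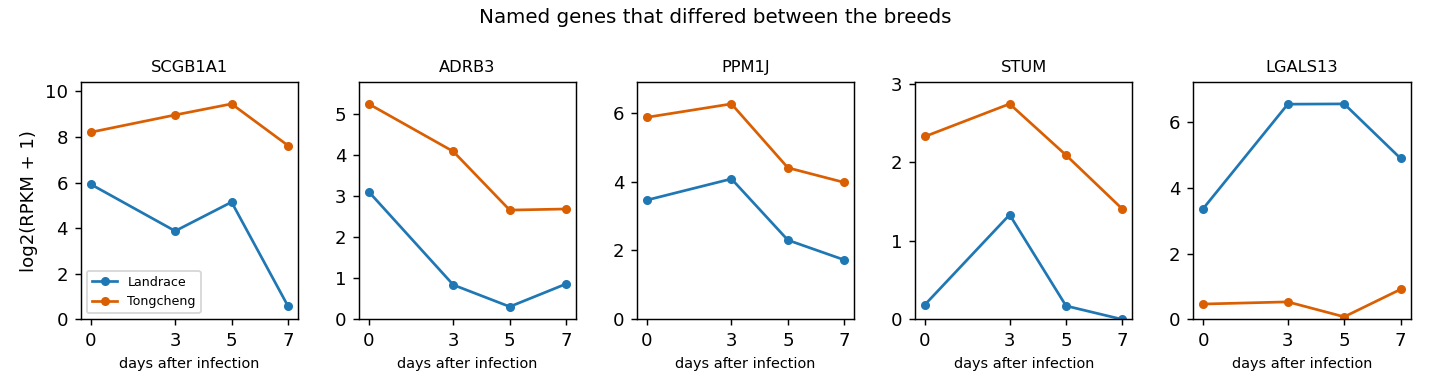
Level of the 5 genes with a symbol that differed between the breeds, as log2(RPKM + 1) against days after infection, 1 pool per point, with Landrace in blue and Tongcheng in orange. SCGB1A1 lies at 197 to 700 RPKM in Tongcheng and 0.498 to 60.2 in Landrace.

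Set day against day, several lists stood apart between the 2 pools taken before infection, among them the interferon-stimulated genes. At 0 dpi erythroid and platelet genes had a median of 2.44 (3 genes), interferon-gamma-induced genes 1.44 (percentile 99.98) and oxidative phosphorylation genes 1.18 (99.67). Mitochondrially encoded genes lay at -2.02, immediate-early genes at -0.88 (percentile 0), smooth muscle markers at -0.80 (0.01) and matrix genes at -0.52 (0.01). The Tongcheng 0 dpi pool had a median log2 of 1.98 over Landrace for the 30 genes (above all 10000 random lists), and the values were -0.18, 0.47 and -0.59 at 3, 5 and 7 dpi. ISG20 stood at 89.2 and 4.27 RPKM, the tryptophan-degrading enzyme IDO1 at 198 and 12.4 and the metallothionein MT1X at 845 and 29.9 in the 0 dpi pools of Tongcheng and Landrace. PRTN3 (-3.48), GNG8 (-3.23) and EGR1 (-3.08) had the lowest log2 ratios there among genes with a symbol. Neutrophil markers lay low in Tongcheng on all 4 days (-0.72, -0.62, -0.84 and -1.04, percentiles 0.01, 0, 0 and 0.02). In the Landrace 7 dpi pool macrophage and monocyte markers had a median of -1.84 against 0 dpi, below all 10000 random lists. Between the breeds these markers lay at 0.83, 0.35, 1.33 and 1.75 and T and NK cell markers at 0.76, 0.54, 0.32 and 1.45. The ends of the list of ratios on the later days are likewise given among genes with a symbol. At 3 dpi they were SCGB1A1 (5.09), KRTDAP (3.42) and ADRB3 (3.24) against LGALS13 (-6.00), RPS21 (-5.31) and CD207 (-4.37). At 5 dpi they were SCGB1A1 (4.31), MARCO (4.15) and FCN2 (4.07) against UBL5 and LGALS13 (-6.46 each) and VPS9D1 (-5.18). At 7 dpi they were SCGB1A1 (7.04), MARCO (6.17) and BANF1 (4.91) against RETN (-5.08), FMO1 (-4.68) and RBP4 (-4.68). Higher and lower genes by 2-fold numbered 2264 and 659, 2187 and 507, 622 and 548, and 926 and 1396 on the 4 days. They were 1388 and 1157, 1107 and 1055, 454 and 754, and 1277 and 952 after median-of-ratios scaling, with no replicate check.

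**Figure D3:**
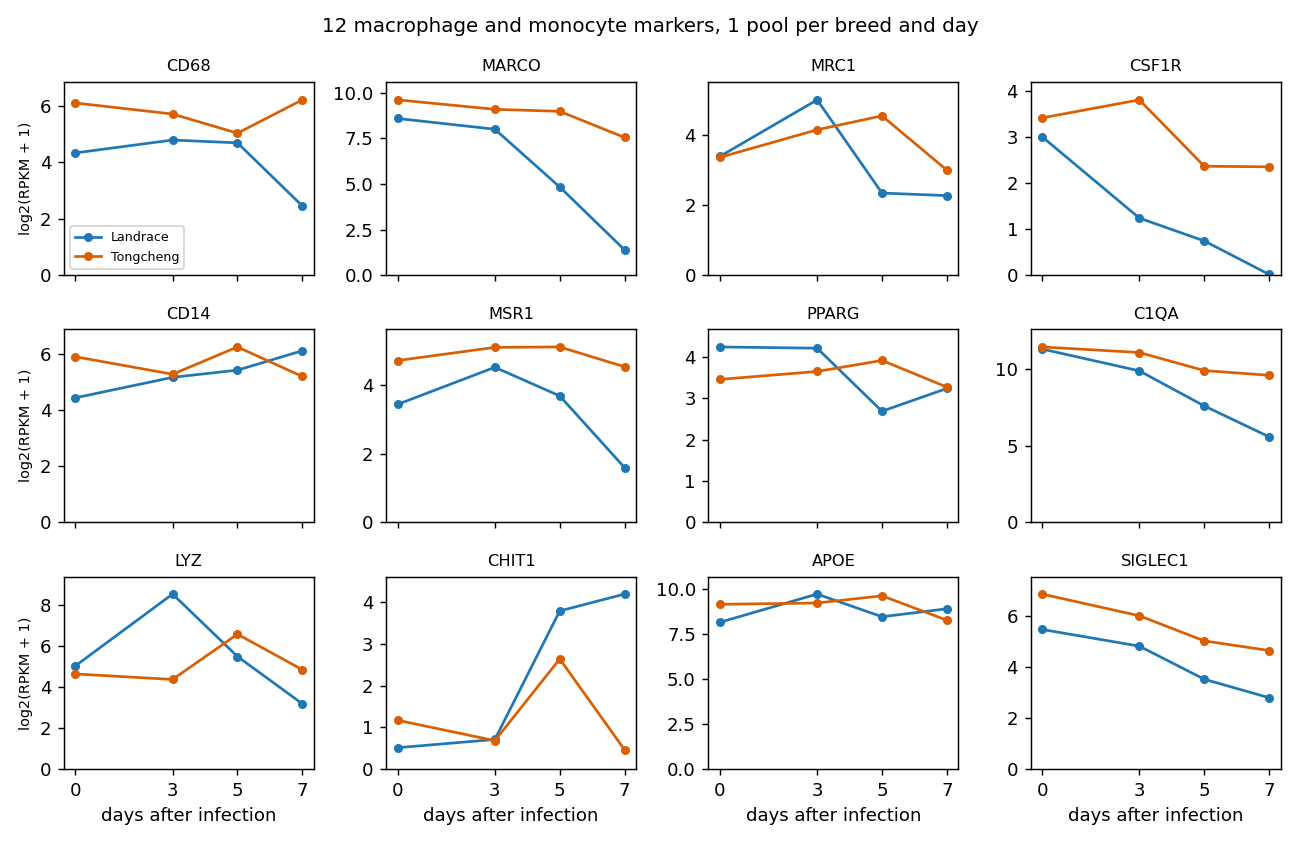
Level of 12 macrophage and monocyte markers as log2(RPKM + 1) against days after infection, 1 pool per point, with Landrace in blue and Tongcheng in orange. MARCO lies at 386 RPKM at 0 dpi and 1.60 at 7 dpi in Landrace, and at 785 and 187 in Tongcheng.

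**Figure D4:**
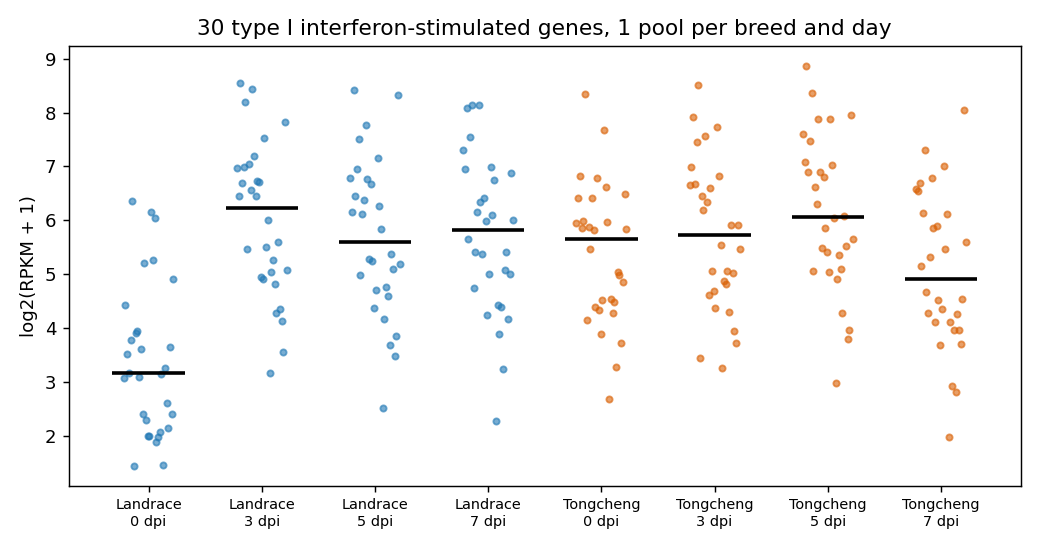
Expression of 30 type I interferon-stimulated genes as log2(RPKM + 1) in each of the 8 pools, 1 point per gene and a black line at the median. The median is 3.16 in the Landrace 0 dpi pool, 5.65 in the Tongcheng 0 dpi pool and 4.91 to 6.22 in the 6 infected pools.

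Whether the response to infection differed between breeds was tested by the interaction. All 30 interferon-stimulated genes had a smaller difference in Tongcheng (median -2.15, limma camera adjusted p = 1.33e-20, 0.5 with an estimated correlation), and 10 passed when adjusted over the list alone, RSAD2 at -4.04 ± 0.865, ISG20 at -4.47 ± 1.25, IFIT1 at -3.84 ± 1.09 and OASL at -3.38 ± 0.961. Each breed's response rests on 1 pool at 0 dpi, and the Landrace pool lay apart from the rest. The interaction subtracts the breed difference at 0 dpi from that after infection, so a difference at 0 dpi alone can give such values. Oxidative phosphorylation genes were negative in 17 of 17 members (median -1.28, 0.000112, 0.695 with an estimated correlation). Airway epithelial markers were negative in 15 of 17 (-1.11, 0.00308, 0.5). Immediate-early genes, which respond within minutes to stimuli including tissue handling, were positive in 11 of 12 (median 1.11, EGR1 4.13 ± 1.31 and FOS 3.11 ± 1.14; 1.16e-05, 0.5 with an estimated correlation). Smooth muscle markers were positive in 6 of 6 (1.39, 0.00308, 0.695), matrix genes in 12 of 16 (0.85, 0.00189, 0.695) and proliferation genes in 12 of 15 (0.41, 0.0435, 0.695; limma camera adjusted p = 0.0591 with the length trend removed). None of their members passed over the list alone. The 13 mitochondrially encoded genes, a list added after seeing the data, were positive in 12 (median 1.87). Their limma camera p, without adjustment, was 2.26e-05, and 0.242 with an estimated correlation. By limma 0 genes were called, with 379 at an unadjusted p under 0.05, below the 687 expected by chance, 0 in limma voom, and 74 (41 higher, 33 lower) without the filter on low values. The genes named by the rule, none of which passed, included EGR1, ISCU (3.34), SF3A1 (3.28) and SCGB1A1 (3.21, and 1.90 without the Landrace 7 dpi pool) as higher. Those named as lower were DEFB1 (-4.73), S100A6 (-4.60), RPS21 (-4.50), ISG20 and FAM167B (-4.31). The median of all genes, -0.185, was -0.042 after median-of-ratios scaling.

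The breeds' log2 ratios to their own 0 dpi pools correlated across the 13739 genes at 0.539, 0.711 and 0.293 at 3, 5 and 7 dpi, with covariances of 0.49, 0.753 and 0.238. Genes are not independent replicates, and the breeds share no 0 dpi pool. At 5 dpi, 1268 genes were at least 2-fold lower in both breeds against 397.9 for independent lists, and 714 higher in both against 179.2. At 7 dpi the shared numbers were 435 against 237.1 and 344 against 119.9, with 199 genes higher in Landrace and lower in Tongcheng.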

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

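The tests of technical explanations given here were chosen only after the results were seen, as was the list of mitochondrially encoded genes; the other gene lists and the interaction test were set beforehand.

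The response to infection differed between the breeds in the interaction test for several gene lists, at the preset correlation only. That test subtracts the breed difference at 0 dpi from that in the infected pools. It cannot tell a different response from a different level before infection. The median of Tongcheng minus Landrace was -2.15 for type I interferon-stimulated genes, -1.11 for airway epithelial markers, -1.28 for oxidative phosphorylation genes, 0.855 for extracellular matrix genes, 1.39 for smooth muscle markers, 0.41 for proliferation genes, 1.11 for immediate-early genes and 1.87 for mitochondrially encoded genes. Hypoxia and glycolysis genes stood at -0.37, EGR1 at 4.13 and ISCU at 3.34. They are listed only because their signs were opposite in the breeds on all 3 infected days; that difference in sign was not tested, and the limma interaction had an adjusted p of 1.0 for each of these genes.

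Interferon-stimulated genes were higher in the Tongcheng than in the Landrace 0 dpi pool, by a median of 1.98, a difference that the interaction holds by construction. The tables argue against gene length and library scaling as the whole cause: removal of the length trend took away a median of -0.07 (SE over genes 0.03), leaving 2.05, and the median was 1.69 (0.13) after median-of-ratios scaling. An exchange of the Tongcheng 0 dpi pool with an infected Tongcheng pool cannot be told apart, because the lowest infected Tongcheng pool lay 1.46 (0.31) above the Landrace 0 dpi pool, too near the bound of 1 set for that test. With 1 pool per breed before infection, a difference between the breeds and a state of these particular pigs also stay open, and no test here separates them.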

How the results depend on the processing

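Fits of limma voom on worked-back reads, removal of the length trend and list tests without the Landrace 0 dpi pool were chosen after seeing the data; all other alternatives were set before the data were examined. Of the counts and correlations recomputed, 99 values stayed within their limit and 104 moved. No limit was set for the correlations, so all their alternatives count as moved, while ratio counts without a filter could not change. For the genes named or shown as list members, 4501 of 5056 values kept direction and side of the threshold. A further 378 lost the call, 162 gained it and 15 reversed. The infection and interaction tests called no gene and hold 793 and 635 of the kept values. Among called genes, TOMM7 at 3 dpi kept its call in 7 of 19 alternatives and SNRPF at 5 dpi in 12 of 19. MS4A7 at 7 dpi kept it in 8 of 19 and LGALS13 between the breeds in 16 of 20. Where no construction shows it, the cause was not tested.

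With a pseudocount of 0.1 the number of genes called was 1 for infection, 13, 283 and 0 for 3, 5 and 7 dpi. Without a filter on low values, where more genes are tested, it was 12 for infection, 0, 0 and 0 for the days, 0 for breed and 74 for the interaction. Median-of-ratios scaling gave 0, 0 and 0 for the days and 3 for breed, and quantile normalization 0, 306, 0 and 7. Without the trend the counts were 13 at 3 dpi and 0 at 7 dpi. At an adjusted p under 0.1 limma called 768, 2511 and 28 genes for the days and 55 for breed. Without breed in the model the days gave 1, 0 and 0. Breed gave 3 without day and 9 on infected days only. Voom gave 0 at 3 dpi, 2 at 7 dpi and 53 for breed, and removal of the length trend 0, 0, 0 and 9. The gene lists called were 0 with an estimated correlation in all 6 comparisons, and with fry 0 for infection and for each day, 1 for breed and 1 for the interaction, against 7, 11, 9, 13, 6 and 7; the lists called by fry, pattern recognition receptors and MHC class I, are not among these. With the length trend removed they were 7, 9, 7, 9, 6 and 6. Without the Landrace 0 dpi pool they were 6, 9, 10, 5 and 6, the interaction not being estimable.

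Leaving out 1 pool at a time gave 0 to 4 genes for infection, 0 to 1615 at 3 dpi, 0 to 2136 at 5 dpi, 0 to 124 at 7 dpi, 1 to 50 for breed and 0 to 0 for the interaction, which cannot be estimated without either 0 dpi pool. At 4-fold the ratios gave 1701, 1615 and 730 genes in Landrace, 154, 267 and 327 in Tongcheng, and 356, 266, 202 and 351 between the breeds at 0, 3, 5 and 7 dpi. With a pseudocount of 0.1 they gave 2795 for Tongcheng at 3 dpi, and 1811 and 3511 between the breeds at 5 and 7 dpi. A filter at an RPKM of 1 cannot act on these counts, since a 2-fold ratio of RPKM + 1 already needs that level. At an RPKM of 5 or more in either library they were lower, for example 4848 for Landrace at 3 dpi, 2622 for Tongcheng at 7 dpi and 852 between the breeds at 5 dpi. The correlations of the breeds' responses were 0.502, 0.658 and 0.262 with a pseudocount of 0.1, and 0.573, 0.751 and 0.328 at a mean RPKM of 5 or more.

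Reversed values were few, and the span on leaving out 1 pool at a time is given with each. At 3 dpi ACTA2 ran from -1.67 to 0.092, the latter without the Landrace 0 dpi pool. At 7 dpi HBM ran from -2.40 to 0.21 (without the Tongcheng 0 dpi pool), NDUFB5 from -0.11 (without the Landrace 0 dpi pool) to 2.05 and PLIN4 from -1.33 to 0.40 (without the Tongcheng 7 dpi pool). Without the Landrace 7 dpi pool TAP2 was -0.16, with a highest value of 0.76, and MMP8 -0.33, with a highest value of 3.39. MT3 at 7 dpi ran from -0.73 to 0.49, the latter without the Tongcheng 0 dpi pool, and was 0.28 without the Tongcheng 7 dpi pool. It was 0.76 with a pseudocount of 0.1, 0.048 after median-of-ratios scaling, 0.073 after quantile normalization and 0.47 in voom. In the interaction SIGLEC1 ran from -0.33 (without the Landrace 7 dpi pool) to 0.68, with -0.26 without the Tongcheng 3 dpi pool and -0.25 with the length trend removed. No paired analysis was possible because the replicate number 1 only names each library and pairs no animals, and the breed test sets pools of the same day against each other through its day term.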

Other observations

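The tests of technical explanations in this part were chosen only after the results were seen.

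Of 12 alveolar epithelial markers 10 were negative at 5 dpi. Adjusted over the list alone, the surfactant protein gene SFTPB (-1.56 ± 0.537), the lipid enzyme LPCAT1 (-1.58 ± 0.492) and the phosphate transporter SLC34A2 (-1.45 ± 0.497) fell and SFTPD, a surfactant lectin that binds microbes, rose by 1.64 ± 0.518, while none of the 12 passed over all genes in limma (camera adjusted p = 0.256, and 0.588 with an estimated correlation). At 7 dpi SFTPD rose by 2.18 ± 0.518 over the list alone, while 2 other members fell and 9 of the 12 were negative. The RPKM of SFTPD went from 50.0 at 0 dpi to 203, 302 and 298 in Landrace and from 73.1 to 103, 121 and 257 in Tongcheng.

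In the Tongcheng 7 dpi pool, against its 0 dpi pool and with no replicate check, T and NK cell markers had a median log2 ratio of 0.70 and inflammatory cytokines and chemokines 0.73, both above all 10000 random lists. CCL2, which attracts monocytes, had an RPKM of 589 there and 26.7 in the Landrace 7 dpi pool. Mitochondrially encoded genes lay at 1.96 in that pool, which had 19.8% of its reads in them. Glucocorticoid-responsive genes of Tongcheng over Landrace lay at 1.04 at 5 dpi (percentile 99.99) and -1.26 at 7 dpi (percentile 0.03). IFNB1, the interferon beta gene, had an RPKM of 0, 1.26, 1.20 and 0.316 in Landrace and 0.108, 0.224, 1.99 and 0.0524 in Tongcheng at 0, 3, 5 and 7 dpi. For a 1 kb gene, 1 read stood for 0.0605 RPKM in the Tongcheng 0 dpi pool and 0.0294 in the Tongcheng 7 dpi pool. The lowest values thus rest on very few reads, and the 0 dpi pools cannot be told apart by this gene.

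At 5 dpi oxidative phosphorylation genes were higher and matrix genes lower, by medians of 1.12 and -1.40. Against gene length as the whole cause, removal of the length trend took away medians of 0.09 (SE over genes 0.07) and -0.24 (0.07), leaving 1.0 and -1.25. Against the Landrace 0 dpi library as the only source for matrix genes, the Tongcheng pools by themselves had a median of -1.01 (0.29), below all 10000 random lists. For oxidative phosphorylation genes that source cannot be told apart: the Tongcheng pools had 0.38 (0.15, with correlated genes taken as independent), at percentile 93.8 of random lists. Without that library the list median was 0.53. With all libraries the limma camera adjusted p was 0.588 at an estimated correlation. A change in the cell types sampled and the size of the part that library has in the Landrace values stay open.

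Macrophage markers were lower in the Landrace 7 dpi pool than in the Landrace 0 dpi pool, by a median of -1.84. Even dilution of all resident cells by incoming cells would lower alveolar epithelial markers as much, and these lay 1.84 (SE over genes 0.75) higher, while neutrophil markers had a median of 1.17 (percentile 99.89). Against gene length as the whole cause, removal of the length trend took away a median of -0.11 (0.06), leaving -1.71. Within the list CD14, APOE and CHIT1 went the other way, at 68.1, 479 and 17.2 RPKM against 20.6, 284 and 0.428. A change in the mix of cells, with more neutrophils or fewer macrophages, and lower expression in each cell are not separated by any test here, and the values rest on 1 pool on each day.

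The breed test has day in its model, so the splits of the 8 libraries comparable with the real one have 1 pool of each day in each group. There are 8 of them, too few for a share under 0.05. For genes the real split gave 16, as did 1 of the 8, itself, and the highest other gave 1. For gene lists the real split gave 6, the lowest count of the 8, and the others gave 8 to 17. Of the other splits, which are uneven over the days, 24 could be fitted and 3 could not, with at most 2 genes and 17 lists. The cause of the high list counts was not tested.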
